A study of Homo sapiens with 6 samples.

How the data were processed

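Total RNA from 6 samples of THP-1 cells was hybridised to Affymetrix Human Gene ST expression arrays, per the labels' protocols and the series' design text. Cells had been transduced with a hairpin vector against RKIP or with the empty vector, and both were selected and maintained in 1.5 µg/mL puromycin. For each array 250 ng of total RNA entered the biotin labelling, per the labels. The single deposited table held 53617 rows of values on a log2 scale, 1 column per array and with no column left unused. The authors' summarisation, background correction and normalisation method, and the genome build, are not given in the sources used here. That the deposited values are log2 was read from their range, 0.72 to 14.0, and from array medians between 4.06 and 4.10. The scanner files and any call of detection above background were not used here, so a dim gene could not be told from an absent one. A group mean below the median of all rows, 4.08, is described as dim, since changes of dim genes are compressed by background.

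Rows were named through the array annotation supplied with the series, which gave exactly 1 gene symbol to 16098 rows, several to 0 rows and left 37519 rows unnamed here. All named rows were matched by gene number to the RefSeq gene table of GRCh38.p14, from which gene type was taken. No coordinate is given, because the build behind the array annotation is not named. For each of the 14884 genes the probe with the highest mean over all 6 arrays was kept, which mattered for 779 genes with several probes. Of 150 called genes with other probes, 42 had another probe called in the same direction and 0 had one called in the opposite direction. For TNF, HSPA1A and SNAR-C1 another probe had the same log2 change as the kept one. Such probes are no independent check.

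The comparison was RKIP shRNA minus control, 3 arrays against 3, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with its default prior and no filter on brightness. The fit had 7.01 total degrees of freedom, of which 3.01 came from the prior. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and 4806 genes had an unadjusted p under 0.05. No array date, slide or batch is in the labels, so no batch could be tested. The group labels were checked on PEBP1, also with an exact permutation test over 20 assignments. No 2 arrays were duplicates: pairs shared identical values in 58 to 144 rows of the table.

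A total of 31 gene lists was fixed before the data were examined, with 595 entries of which 350 were measured. Older symbols were matched only where they are no gene's current symbol and the old name of 1 gene. The 27 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera also uses only the residual degrees of freedom of the arrays, so its p-values rise for that reason too. Fry asks whether a list's genes move, on balance, one way, and does not compare them with other genes. The genes named were also set by a rule fixed beforehand: PEBP1, the 14 protein-coding genes with the largest rise and the 14 with the largest fall among called genes whose groups did not overlap, up to 3 non-coding genes each way, and in each list the 4 called members with the smallest p or, where none was called, the 2 with the largest change. CD14, CD86, CD4 and MEIS1 were named outside this rule, as were the further genes of the closing section.

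The alternatives were quantile normalisation, median centring, a trended and robust prior, array weights, the replicate number as a block, leaving out rows below the median brightness, all rows whether named or not, the mean of a gene's probes, an ordinary t statistic, stricter thresholds and leaving out each array in turn. The replicate numbers did not pair the arrays, and that check is given with the alternatives. The fit was tested on simulated arrays with the real means and residual spread of the 14884 genes and 200 changed genes. It recovered 37.3% of genes changed by 0.5, 89.6% of those changed by 1 and 97.0% of those changed by 2 on the log2 scale, and 2.61% of its calls were false. Only these 200 genes were changed, whereas 20.2% of genes were called in the real data. The adjusted threshold depends on that share, so these rates do not carry over to the real fit. With simulated lists, camera called the 1 raised list and 0 of 20 unchanged lists. The simulated genes were drawn independently, whereas the real G2/M list had an estimated correlation of 0.24. The simulation therefore does not show how camera behaves on lists of correlated genes. Figures were drawn with matplotlib 3.10.9.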

Results

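Gene expression was measured in THP-1 cells, an established human line of acute monocytic leukaemia, after stable transduction with a lentiviral vector that either expressed a short hairpin RNA against RKIP or was empty. RKIP, the Raf kinase inhibitor protein, is encoded by PEBP1 and is known to restrain signalling through MEK and ERK. The comparison asked which genes change when RKIP is depleted in acute myeloid leukaemia cells. Each group held 3 arrays labelled as biological replicates. Nothing in the labels says whether these came from separate transductions or from repeat cultures of one transduced population, so the p-values measure the spread between these arrays, which may be partly technical. A value could be tied to 1 gene name for 14884 genes, of which 11916 were protein-coding. Array medians over all rows lay between 4.06 and 4.10 on the log2 scale. Over the named genes, arrays of the same group correlated at r = 0.994 to 0.996 and arrays of different groups at 0.987 to 0.988 (correlations across genes, which are not independent replicates). The leading principal component held 58.5% of the variance and separated the groups. With 3 arrays per group, their number limits the precision of every value below, and errors of log2 changes are standard errors from limma.

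The targeted gene was lower in every RKIP shRNA array. PEBP1 stood at 9.68 ± 0.14 in control cells and at 8.22 ± 0.04 in RKIP shRNA cells (log2 values, mean ± SD, n = 3 each). It fell by 1.46 on the log2 scale (SE 0.09, limma adjusted p = 0.000228), which left 36.4% of the control level, with a 95% interval from 31.6% to 42.1%. An exact two-sided permutation test of this gene alone gave p = 0.10, the smallest value that 3 arrays against 3 allow. PEBP1 ranked 28 among the genes that were lower in RKIP shRNA cells when these were ordered by the size of the change.

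**Figure D1:**
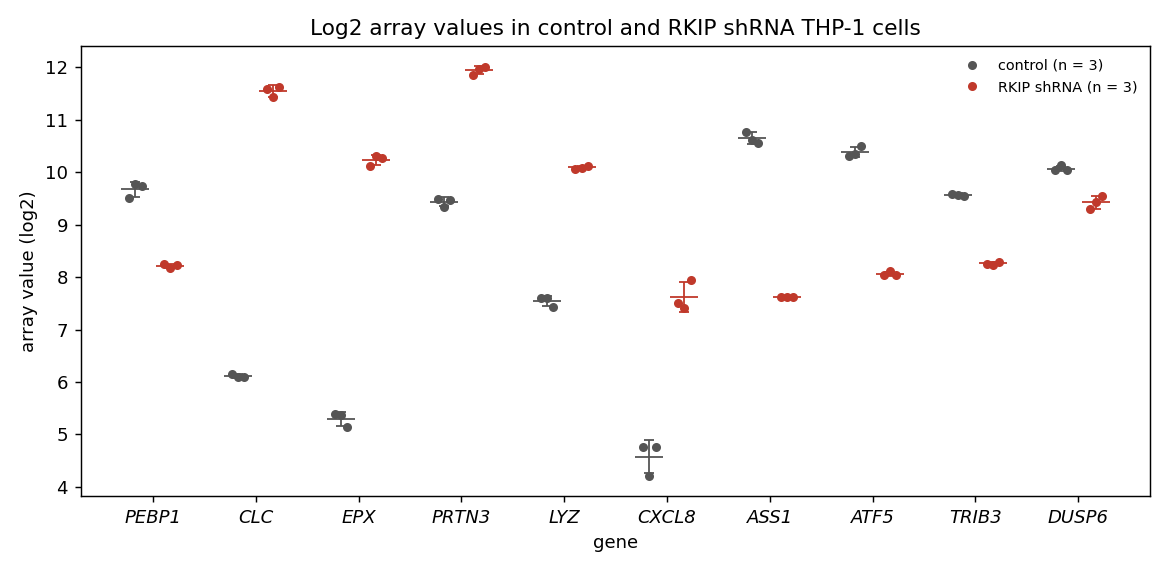
Log2 array values (vertical axis) of 10 genes in the 3 control arrays (grey) and the 3 RKIP shRNA arrays (red); points are arrays, and bars give the mean and SD. The groups do not overlap for any of these genes; PEBP1 lies at 9.68 in control and 8.22 in RKIP shRNA cells, and CLC at 6.12 and 11.55.

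Expression differed widely between the groups: 1495 genes were higher and 1515 were lower in RKIP shRNA cells, together 20.2% of the genes tested (limma, Benjamini-Hochberg adjusted p under 0.05). Most of these differences were small. The median absolute log2 change among them was 0.46, and 61 higher and 127 lower genes differed by at least 2-fold. The groups did not overlap for 37.9% of all genes, where chance gives 10% for 3 arrays against 3. The count of higher genes fell to 969 without control replicate 2, to 983 without control replicate 3 and to 963 without RKIP shRNA replicate 1.

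Among genes with a name, the largest rises were in CLC and EPX. CLC, which encodes the Charcot-Leyden crystal protein of eosinophils and basophils, rose from 6.12 ± 0.03 to 11.55 ± 0.11 (SD, n = 3 each), a log2 change of 5.43 ± 0.08 or 43.1-fold (adjusted p = 4.5e-07). EPX, the eosinophil peroxidase, rose from 5.30 ± 0.13 to 10.23 ± 0.10, or 30.6-fold (adjusted p = 1.8e-06). PRTN3, the azurophil granule protease proteinase 3, rose 5.68-fold to 11.94 ± 0.07, and LYZ, which encodes lysozyme, rose 5.85-fold to 10.09 ± 0.03. A second LYZ probe rose by 3.43 on the log2 scale. The chemokine genes CXCL8 and CXCL10 rose 8.27-fold and 5.28-fold. The myeloid nuclear antigen gene MNDA rose 6.66-fold, and TYROBP, a signalling adaptor of myeloid receptors, rose 5.19-fold. HGF, the hepatocyte growth factor, rose 4.39-fold and ANXA1, annexin A1, rose 4.34-fold. The metallothionein gene MT1X rose 3.22-fold, the chitinase-like gene CHI3L1 3.19-fold, the zinc finger gene ZNF850 3.22-fold, and IL1RL1, an interleukin receptor gene, 3.15-fold. CXCL10 and IL1RL1 lay below the median of all rows, 4.08, in control cells, so their folds rest on dim values there. CXCL8, MNDA and CHI3L1 lay little above it in control cells, at 4.58, 4.57 and 4.57, so their folds may be compressed too. Among non-coding genes, SNAR-B1 and SNAR-C1 rose 3.21-fold and 2.76-fold, and PCED1B-AS1 rose 2.68-fold from a dim control value. The SNAR genes are near-identical copies, so their signals cannot be assigned to single members. PCED1B-AS1 is named as antisense to a coding gene, and no source used here states whether its probe reads one strand.

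The largest falls of named genes included ASS1 and TM6SF1. ASS1, the argininosuccinate synthase of arginine synthesis, fell by 3.03 on the log2 scale (SE 0.08, adjusted p = 8.9e-06), which is 8.17-fold. TM6SF1 was 7.40-fold lower, and the transcription factor gene ATF5 was 5.01-fold lower, at 10.39 ± 0.10 in control and 8.06 ± 0.04 in RKIP shRNA cells (SD, n = 3 each). NOG, the BMP antagonist noggin, was 4.61-fold lower, ACSM3, a medium-chain acyl-CoA synthetase, 4.20-fold lower, and HHIP, the hedgehog-interacting protein, 3.86-fold lower. GPR174 was 3.45-fold, FSIP2 3.44-fold and UNC5B, a netrin receptor, 3.34-fold lower. GAB2, a docking adaptor in RAS and PI3K signalling, and MFAP4 were each 3.25-fold lower. C5AR1, the complement C5a receptor, was 3.16-fold lower, while HOXB9 and ANGPT1, which encodes angiopoietin 1, were each 3.12-fold lower. HHIP and C5AR1 lay below the median of all rows in RKIP shRNA cells, and TM6SF1 and FSIP2 lay little above it there, at 4.11 and 4.19. A second FSIP2 probe gave a log2 change of 0.17 and did not share the fall. The microRNA genes MIR548I2, MIR548AG2 and MIR548I1 were 4.58-fold, 4.47-fold and 4.37-fold lower. They belong to a family of near-identical members, so their signals cannot be assigned to single members. A second MIR548I2 probe gave a log2 change of 0.00 and did not share the fall, whereas the other MIR548I1 probes had log2 changes from -1.40 to -0.61.

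**Figure D2:**
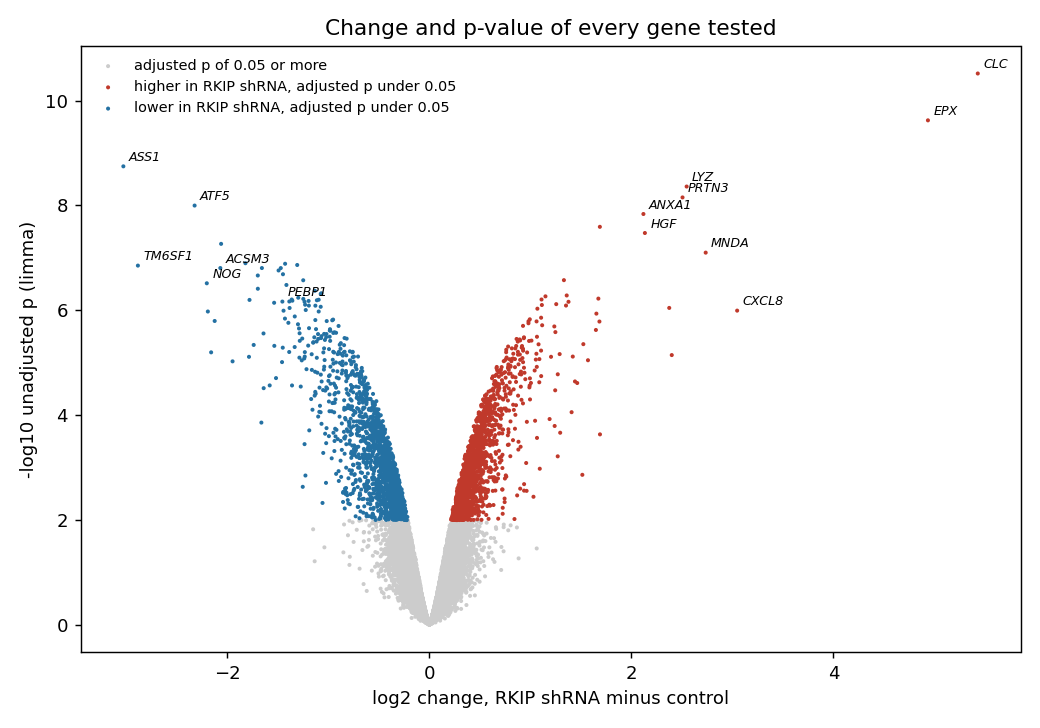
Log2 change in RKIP shRNA cells against control (horizontal axis) and −log10 of the unadjusted limma p-value (vertical axis) for 14884 genes; red marks 1495 genes that were higher and blue 1515 that were lower at an adjusted p under 0.05, and grey the rest. CLC and EPX stand apart at log2 changes of 5.43 and 4.94.

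Transcripts that commonly follow ERK activity did not move one way. Of 21 measured members of the ERK output list, 2 rose, 4 fell and 15 did not pass the test; adjusted over the list alone, 3 rose and 4 fell. DUSP6, the ERK phosphatase gene that ERK itself induces, fell by 0.65 (SE 0.08, adjusted p = 0.0026). MYC fell by 0.42 and the early response gene IER2 by 0.62, while FOSL1, a subunit of AP-1, rose by 0.65 on the log2 scale. The median log2 change of the list was -0.09, and camera, which compares a list with all other genes, gave an adjusted p of 0.31. Among 9 measured components of the RAF-MEK-ERK cascade 1 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.81). These were ARAF at 0.32 and RRAS at -0.51, and their adjusted p-values reached 0.056 and 0.071 when single arrays were left out: ARAF lost its call without control replicate 1 or 3, and RRAS without any 1 control array or without RKIP shRNA replicate 2. Of 9 measured partners of RKIP, CHUK, the IKK alpha kinase, and KEAP1, the inhibitor of NRF2, rose by 0.43 and 0.40 and 7 did not pass (2 rose adjusted over the list alone; camera adjusted p = 0.28).

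Among 11 measured RAS regulators and adaptors, 1 rose and 5 fell, or 2 and 5 adjusted over the list alone. GAB2 fell by 1.70 and RASA2, a RAS GTPase-activating protein, by 0.40, while the adaptor GRB2 rose by 0.46. Camera gave an adjusted p of 0.10 for this list, and 0.030 without RKIP shRNA replicate 3. Of 10 measured AP-1 genes, 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.67). FOSL2 fell by 0.66 on the log2 scale, against the rise of FOSL1.

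Genes induced by NF-kB were higher as a list by camera with its preset correlation between genes (adjusted p = 0.019) but not with an estimated one (adjusted p = 0.23). Of 16 measured members 5 rose, 1 fell and 10 did not pass; adjusted over the list alone, 6 rose and 1 fell. CXCL8, which encodes interleukin 8, rose by 3.05 ± 0.19 and TNF by 1.29 ± 0.11 on the log2 scale (adjusted p = 0.00026 and 0.00062). CCL20 rose by 0.56 and CD83 by 0.66. The list had a median log2 change of 0.17. Interferon-stimulated genes went both ways: 7 of 21 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.31). CXCL10 rose by 2.40, IFIT1 by 1.57 and IFIT2 by 1.44, all 3 from dim control values, whereas TRIM22, a restriction factor gene, fell by 1.07.

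Myeloid lineage genes changed in part. Of 22 measured monocyte and macrophage markers, 4 rose, 2 fell and 16 did not pass, with the same counts adjusted over the list alone (median log2 change 0.09, camera adjusted p = 0.32). LYZ rose by 2.55, TLR4, the lipopolysaccharide receptor, by 1.25, the lysosomal protease gene CTSD by 0.79 and CD68 by 0.37. The 2 that fell were CD86 at -0.90 and CD4 at -0.35. The monocyte marker CD14 was dim in both groups, with a log2 change of -0.06, and did not pass. Of 15 granulocyte markers, 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.31). PRTN3 rose by 2.51 and CTSG, the azurophil granule protease cathepsin G, by 0.51. Among the others, AZU1 at 0.60 lost its call in 5 of 6 fits that left out 1 array, and CSF3R at -0.49 in 3. Of 15 stem and progenitor markers, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.54). SOX4 fell by 1.36 and FLT3, a receptor kinase, by 0.48 to a dim value, while GATA2 and LMO2 rose by 0.56 and 0.48. THP-1 cells carry a KMT2A-MLLT3 fusion, and genes known to be maintained by KMT2A fusions were lower as a list by camera (adjusted p = 0.0010) but not with an estimated correlation (adjusted p = 0.16). Of 11 measured KMT2A fusion targets, 6 fell and none rose, or 7 fell adjusted over the list alone, with a median log2 change of -0.26. CDK6 fell by 0.54 and SATB1 by 0.52. The HOXA genes of this list had no value under a gene name, and MEIS1 at 0.22, dim in both groups, did not pass. MEF2C at -0.42 lost its call in 2 of 6 fits that left out 1 array, and its second probe gave 0.26.

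Part of the cell division genes rose. Of 19 measured G2/M genes 12 rose and none fell, or 15 adjusted over the list alone, with a median log2 change of 0.34. CDC20, an activator of the anaphase-promoting complex, rose by 0.82, the mitotic kinesin gene KIF20A by 0.85, cyclin B1 (CCNB1) by 0.78 and survivin (BIRC5) by 0.57. Of 21 DNA replication genes 11 rose and 1 fell, or 16 and 1 adjusted over the list alone, with a median of 0.24. The GINS complex genes GINS2 and GINS1 rose by 0.59 and 0.53 and the licensing factor gene CDC6 by 0.61, while CDT1, another licensing factor gene, fell by 0.94. Camera gave adjusted p-values of 6.4e-07 for G2/M and 3.8e-05 for replication, and adjusted p = 0.23 for each with an estimated correlation.

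Stress and sterol genes moved in separate directions. Of 12 measured genes of the unfolded protein and integrated stress response, 8 fell and none rose, or 9 adjusted over the list alone (median log2 change -0.34, camera adjusted p = 1.8e-05, and adjusted p = 0.16 with an estimated correlation). TRIB3, a pseudokinase gene induced by ATF4, fell by 1.31, the asparagine synthetase gene ASNS by 0.52, DDIT3, which encodes CHOP, by 0.61 and VLDLR, a lipoprotein receptor gene, by 0.47. Of 7 heat shock genes 5 rose and none fell, also adjusted over the list alone (median 0.67, camera adjusted p = 0.00014, and adjusted p = 0.16 with an estimated correlation). HSPH1 rose by 0.91 and the small heat shock protein gene HSPB1 by 0.67. HSPA1A and HSPA1B rose by 0.72 and 0.68 but are near-identical copies that share sequence, so they may be a single signal. Of 12 cholesterol synthesis genes 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (median 0.35, camera adjusted p = 0.0065, and adjusted p = 0.23 with an estimated correlation). INSIG1 rose by 0.56, DHCR7 by 0.46, NSDHL by 0.59 and squalene epoxidase (SQLE) by 0.54.

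The remaining lists did not pass camera in this fit. With a trended and robust prior the lists of RAS regulators and adaptors, NRF2 targets and the respiratory chain each reached an adjusted p of 0.046. Of 16 apoptosis regulators 6 rose and 2 fell, also adjusted over the list alone, with BAX at 0.78 and PMAIP1, which encodes NOXA, at 0.44 among those that rose and BCL2 at -0.36 among those that fell (camera adjusted p = 0.32). Of 7 p53 targets 2 rose and 1 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.36). Of 9 NRF2 targets 4 rose and none fell, or 5 and 1 adjusted over the list alone, with the peroxiredoxin gene PRDX1 at 1.08, SRXN1 at 0.73 and TALDO1 at 0.39 (camera adjusted p = 0.10). Of 7 respiratory chain genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone, with UQCRC1 at 0.44 and COX5B at 0.43 (camera adjusted p = 0.10). UQCRC2, the 1 that fell, lost its call in all 6 fits that left out 1 array, and CYC1, which rose, in 4. TXN, an NRF2 target that rose, lost its call in 5 such fits, and the p53 targets BBC3 and AEN in 4 and 3. Of 11 glycolysis and hypoxia genes 1 rose and 3 fell, or 3 and 4 adjusted over the list alone, and VEGFA fell by 0.69, the mitophagy receptor gene BNIP3L by 0.72 and NDRG1 by 0.46 (camera adjusted p = 0.28). None of 16 ribosomal protein genes passed in either direction by limma, at an adjusted p over all genes or over the list alone (median -0.01, camera adjusted p = 0.80). Of 17 invasion and metastasis genes 3 rose and 2 fell, also adjusted over the list alone, with CCL5 at 0.64 and SPP1, osteopontin, at 0.88 from a dim control value against HMGA2 at -0.87 and CD44 at -0.45. Their median was -0.03 and their mean 0.01, and camera gave a downward adjusted p of 0.79. Of 9 leukocyte adhesion genes 2 rose and 2 fell, or 2 and 3 adjusted over the list alone, with SELPLG at 0.51 and ICAM3 at -0.46. Their median was 0.09 and their mean 0.02, whereas camera pointed downward with an adjusted p of 0.90. No gene of the histone and MHC class II lists had a named probe, so these lists were not analysed here.

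Markers of cell types that a culture could hold by cross-contamination changed little. Of 6 T cell markers 1 rose (CD5 at 0.39, none adjusted over the list alone), of 6 B cell markers 1 fell (VPREB3 at -0.38, to a dim value) and of 8 epithelial markers 1 fell (KRT18 at -0.29), the latter pair also adjusted over the list alone. Camera adjusted p-values were 0.67, 0.61 and 0.67 for these lists. Directional fry gave adjusted p-values of 0.40, 0.0011 (downward) and 0.33. A second KRT18 probe gave a log2 change of 0.02 and did not share the fall. The 3 calls were not stable: the highest adjusted p on leaving out 1 array was 0.14 for CD5, which kept its call only without control replicate 3, 0.10 for VPREB3, which kept it only without control replicate 2, and 0.082 for KRT18, which kept it only without RKIP shRNA replicate 2 or 3. None of 3 erythroid markers passed by limma, with KLF1 at 0.24, and of 4 fibroblast markers 1 rose, also adjusted over the list alone. This was FN1, the fibronectin gene, at 0.86 from a dim control value. These last lists had too few measured genes for camera.

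**Figure D3:**
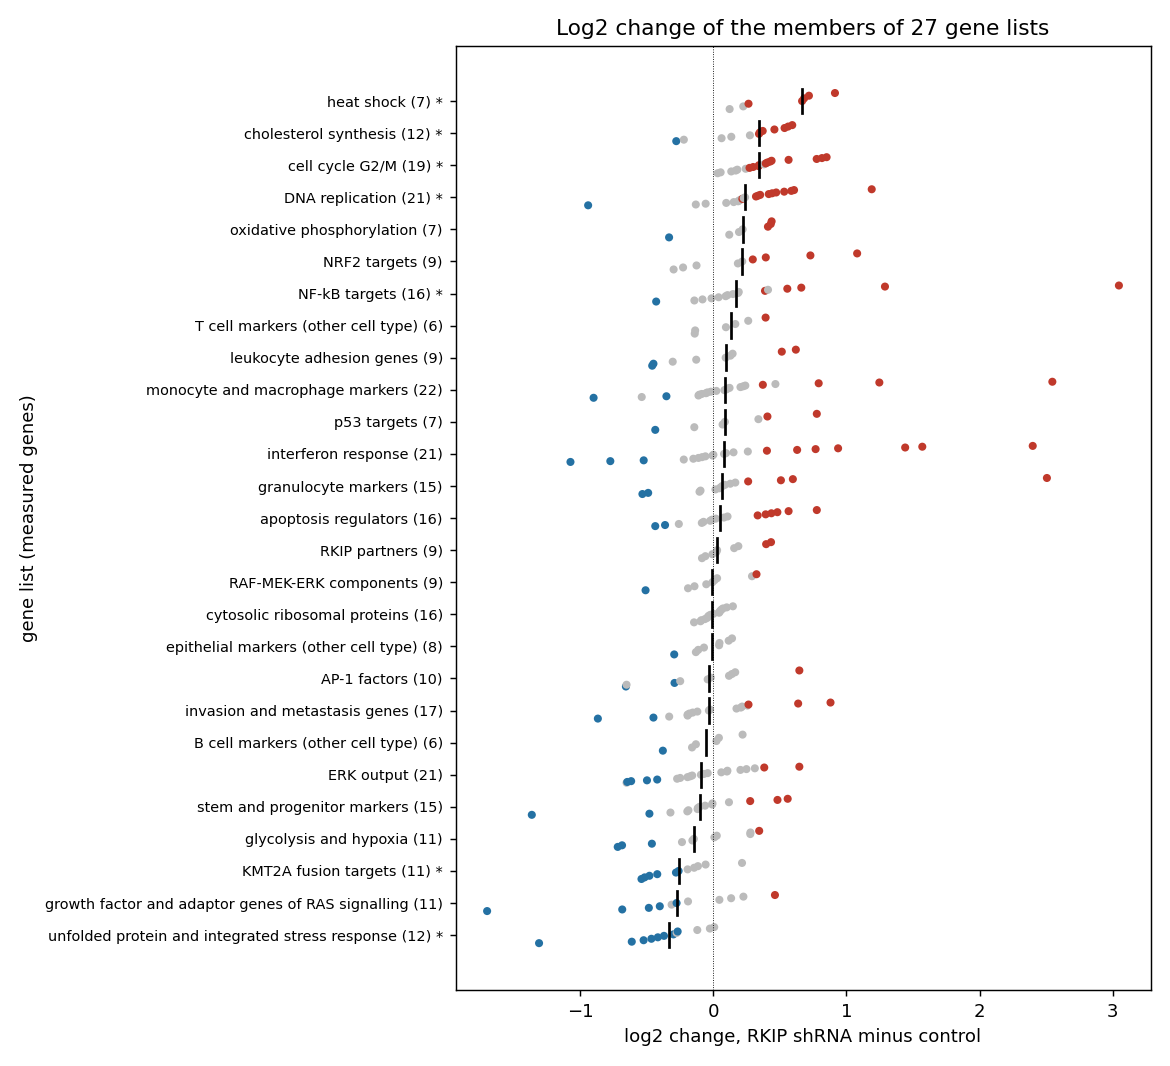
Log2 change in RKIP shRNA cells against control (horizontal axis) of each measured member of 27 gene lists (rows, with the number of measured genes); red points were higher and blue points lower at an adjusted p under 0.05, grey points did not pass, black bars are medians and asterisks mark lists with a camera adjusted p under 0.05, none of which passed with an estimated correlation (lowest adjusted p 0.16). The 7 marked lists run from heat shock, with a median of 0.67, to the unfolded protein and integrated stress response, at -0.34.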

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

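The rows without a gene name, which no comparison above uses, also differed between the groups: 937 of 37519 such rows were higher and 1454 were lower in RKIP shRNA than in control arrays at a limma adjusted p under 0.05. They are listed because they are signals outside the main measurement. The row 16738465 changed most, from 4.12 to 9.58, a log2 change of 5.46 ± 0.12 (SE), followed by 16781602 at 3.11 ± 0.11. The largest falls were in 16701015, at -2.69 ± 0.08, and 17126000, at -2.68 ± 0.19. No explanation of these rows was tested.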

How the results depend on the processing

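The fall of PEBP1 and the changes of the 34 other genes named for their size kept their direction and their call in all 525 values from 15 alternatives; over all 119 named genes, 1674 of 1781 alternative values kept both, and 17 genes lost their call in at least 1 alternative. No gene called both here and in one of these fits had opposite directions in them. Of 1495 higher and 1515 lower genes, 697 and 775 passed an adjusted p under 0.01, and 353 and 534 passed an adjusted p under 0.05 with a change of at least 1.5-fold. With all rows tested, named or not, 1774 of the 3010 called genes kept their call, and 1832 rows were higher and 2439 lower, of which 937 and 1454 had no gene name. Leaving out each array in turn gave 963 to 1212 higher and 1018 to 1270 lower genes, where fewer arrays were tested. The 7 lists past camera stayed at 7 or 8 without single arrays, but became 10 with a trended and robust prior, 0 with an estimated correlation (lowest adjusted p 0.16) and 18 with directional fry, which asks another question. NF-kB targets then had adjusted p = 0.23 with an estimated correlation, which at -0.03 was below the preset 0.01. The unadjusted camera p of this list rose from 0.0048 with the preset correlation to 0.039 with the estimated one. A lower correlation alone would lower p, so this rise came from the fewer degrees of freedom and not from correlated genes. Monocyte and macrophage markers had adjusted p = 0.0011 by fry, upward. B cell markers, a list of another cell type, had the same adjusted p = 0.0011 by fry, downward, so a pass by fry does not mark a lineage. Lists that never passed changed direction: leukocyte adhesion genes with array weights (adjusted p = 0.98) and, on leaving out arrays, at 0.68 to 0.98, AP-1 factors at 0.30 to 0.88, invasion genes at 0.57 to 0.91 and ribosomal proteins at 0.27 to 0.99; the log2 change of AHSP ranged from -0.051 to 0.12. The cause of these reversals was not tested. Arrays with the same replicate number did not deviate together (correlations of -0.02 to 0.02, and 3 of 6 arrays closest to their own number), so the numbers do not pair them; with the replicate number as a block 1033 genes were higher and 1109 lower, no list changed its call and 7 named genes lost theirs. Without a measure of detection, the array signal limits what can be said of dim genes, which lay below the median of all rows in the dimmer group for 252 of the 3010 called genes.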

Other observations

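CTH, SDF2L1, MANF, CD48, CD37, IL18, MT2A, MT1E, SEL1L, XBP1 and ATF4 were chosen after their values were seen. The lists of other ATF4 targets and other chaperone genes were written before, and the members named here were picked from them afterwards. CTH, the cystathionine gamma-lyase gene, fell by 1.49 ± 0.07 (log2, SE). Of 13 measured ATF4 targets outside the fixed stress response list 7 fell, none rose and 6 did not pass: the aminoacyl-tRNA synthetase genes WARS1, CARS1 and SARS1 fell by 0.82, 0.66 and 0.64, while MARS1 at -0.04 and NARS1 at -0.11 did not pass. SDF2L1 rose by 1.52 ± 0.12 and MANF by 1.11 ± 0.07. Of 8 other measured chaperone genes of the endoplasmic reticulum 5 rose, none fell and 3 did not pass. CRELD2 rose by 0.95 ± 0.09 and the calreticulin gene CALR by 0.60 ± 0.07. CANX at 0.08 and HYOU1 at 0.11 did not pass, where a second HYOU1 probe gave 0.34. These 8, called chaperone genes here, include the translocon genes SEC61B at 0.41, which passed, and SEC61A1 at 0.21, which did not. The B cell and leukocyte surface genes CD48 and CD37 fell by 1.43 and 1.38, and the cytokine gene IL18 by 1.39. The metallothionein gene MT2A rose by 0.60 beside MT1X at 1.69, while MT1E had a log2 change of -0.12 and did not pass.

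In the 3 patterns below, the test of divergence between the populations, that of the granulocyte list and that of the chaperone genes against lists matched on level were chosen after their results were seen, as was the rule that an interval must clear the matched range. Bootstrap intervals of list medians resampled the genes of a list with the arrays held fixed. They treat these genes as independent and hold no error between arrays. The first pattern is the number of changed genes. Only differences in distribution that remained in the deposited values could be tested: 3101 genes passed after quantile normalisation against 3010 before. The array medians already lay between 4.06 and 4.10, so this normalisation could change little. Whether larger differences between the arrays were removed before deposit is not known, so this explanation is not settled. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05; the real split gave 1495 higher and 1515 lower genes and 7 lists, the highest other split gave 0 genes in either direction and 6 lists, and 1 split of the 10 reached each real value. Knockdown of RKIP and divergence of the transduced populations for other reasons, such as outgrowth of a subclone or off-target effects of the hairpin, cannot be told apart: the leading component, with 58.5% of the variance, separates the groups under either, and the labels name a single hairpin construct and no rescue.

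The second pattern is the rise of the granule genes CLC, EPX, PRTN3 and LYZ. Eosinophils or basophils in the RKIP shRNA cultures, which puromycin selection should remove, were tested on 8 measured genes of these cells other than CLC and EPX. Their median log2 change was -0.022 (95% bootstrap interval -0.15 to 0.52) with GATA2 and HDC higher, which lies under the change of 1 set beforehand as excluding this source. That bound was too lenient, because only 3 of the 8 lay above the median of all rows and the most abundant genes of the list, such as PRG2 and RNASE2, were not analysed here; the question stays open. A gain of the fixed granulocyte list as a whole is not settled either, with a median of 0.067 (interval -0.10 to 0.26). A change of granule gene expression within the RKIP shRNA cells is an untested hypothesis.

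The third pattern is the fall of ATF4 targets beside the rise of chaperone genes. A dependence of the change on signal level is argued against for the fall, in these arrays and with genes taken as independent. The median of the stress response list was -0.34 (95% bootstrap interval over its genes -0.49 to -0.19). This lay below the 95% range of 10000 random lists matched on mean level, -0.16 to 0.21. For the rise a dependence on signal level stays open. The median of the 8 other chaperone genes, 0.30, lay above the range of matched lists, -0.20 to 0.25. However, its interval, 0.11 to 0.60, overlapped that range. Lower ATF4 output is consistent with 13 other ATF4 targets, which had a median log2 change of -0.24 (interval -0.64 to -0.15, camera p = 7.3e-06, and p = 0.048 with an estimated correlation). ATF4 itself, at -0.28, did not pass (limma adjusted p = 0.051). A higher load of the endoplasmic reticulum stays open. The 8 other chaperone genes had a median of 0.30 (interval 0.11 to 0.60, camera p = 0.00016, and p = 0.054 with an estimated correlation). The camera p-values of both lists are not adjusted over lists, and 0.048 and 0.054 hardly differ, so they do not set one explanation above the other. In contrast to the 8 chaperone genes, of the genes that such a load is known to induce, SEL1L fell by 0.42 and DDIT3 by 0.61, and XBP1 at -0.03 did not pass. All of these belong to the stress response list whose fall is part of this pattern, so they are no separate test. HSPA5, HSP90B1, DNAJB9 and HERPUD1, also in that list, had no value under a gene name. Whether the fall and the rise follow from RKIP, from culture density or nutrients, or from the divergence above is open, since no value here decides between them.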
